A study of Mus musculus with 4 samples.

How the data were processed

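RNA was measured in hearts of 4 mouse embryos at E18.5, all on a C57BL/6 background and homozygous for a floxed Adar1 allele, per the labels. Adar1, listed under the symbol Adar, encodes an enzyme that converts adenosine to inosine in RNA. Control embryos 47 and 50 carried no Nkx2.5-Cre allele, and mutant embryos 51 and 54 carried 1. The groups were taken from the sample titles, which the deposited column headers match, since the genotype entry of the Cre-positive embryos reads wildtype and KO at once. Nkx2.5-Cre puts the Cre recombinase, which recombines DNA between the loxP sites of a floxed allele, under a gene of the early heart. Per the labels' protocols, total RNA was extracted with Trizol and sequenced as paired ends of 150 bp on a HiSeq 4000, from a directional poly(A)-selected library. Each library is labelled as a separate embryo, so the p-values rest on the spread between embryos, from 2 per group. The gene test also draws each gene's variance toward a trend over all genes, so part of that spread comes from other genes.

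The submitters' processing notes name fastp 0.20.0, STAR, edgeR 3.10, DESeq and the build GRCm38. The step each tool made, the counting tool, its strand setting and the annotation are not given in the sources used here. The authors deposited 1 table of 14936 genes. Its 4 value columns are CPM per the file headers, a read signal that the authors scaled to effective library sizes, since the columns sum to between 935156 and 1034350. The column of mean log2 CPM and the per-gene p-value and FDR columns are the authors' own, per the file headers. The deposited logFC column was not a log2 ratio of mutant to control. Its median ratio to the log2 ratio of the group means was 0.500 over 1962 genes, with a 5th percentile of 0.493 and a 95th percentile of 0.504, so fold changes were computed here from the CPM values. No column of per-sample values was left unused. Genes with low values are absent from the table, in which the smallest row maximum is 2.29 CPM.

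Every CPM value was a whole multiple of 1 step per column, within a tolerance of 0.001, for 100% of values. Whole reads per gene were recovered from those steps. The table held 8998872 and 7457103 reads in control libraries 47 and 50, and 8593443 and 8444488 in mutant libraries 51 and 54. These are reads of the listed genes and not the full sequencing depth. A single read was worth between 0.109 and 0.138 CPM. A group at 0 was given a floor of 3 reads per library, and such bounds and counting intervals cover counting error only. The deposited scaling equalled the RLE factors that edgeR and DESeq2 compute from the recovered reads. The replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 8.36 in the controls and 24.6 in the mutants, so no library was counted as a duplicate.

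Gene symbols came from the GENCODE M21 names for the table's Ensembl identifiers, of which 14916 matched and 20 did not. The deposited table stored 20 symbols as dates, and all 20 were restored from their identifiers. Positions are GENCODE M21 positions on GRCm38.

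The test had been designed for counts, with a second form for normalized values. Because the deposited values are normalized, the second form was used. Log2(CPM + 1) values of the 14869 genes with at least 1 CPM in 2 or more libraries were compared between the groups with limma-trend (limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Genotype was the only term, since the labels name no batch. Fold changes are mutant minus control on the log2(CPM + 1) scale, which understates the change of genes with low values. Errors of fold changes are standard errors from limma, and errors of CPM are standard deviations of 2 libraries. A permutation of 2 against 2 libraries cannot give a two-sided p below 0.333, so no permutation test was used.

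Before the data were examined, 38 gene lists were fixed. They cover interferon-stimulated genes, double-stranded RNA sensing, MHC class I antigen presentation, inflammatory cytokines and chemokines, the integrated stress response, endoplasmic reticulum chaperones, p53 targets and cell death. Others hold genes of the cell cycle, the sarcomere, calcium handling, cardiac transcription factors, stress markers, fatty acid oxidation, oxidative phosphorylation, the mitochondrial genome, glycolysis and hypoxia, extracellular matrix, immediate early genes, heat shock proteins, histones and ribosomal proteins. The rest hold markers of fibroblasts, epicardium, endothelium, lymphatic endothelium, smooth muscle, macrophages, neutrophils and mast cells, lymphocytes, erythroid cells, platelets, Schwann cells and neurons, skeletal muscle, lung and airway, liver, brown fat and sex. The 34 lists with at least 5 tested members, the sex list aside, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34. Camera with an estimated correlation and fry were the alternatives for lists. The estimated form rests on the few residual degrees of freedom that 4 libraries leave, so it has little power after adjustment over the 34.

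The named genes were also fixed beforehand. They are Adar, Adarb1, Adarb2 and Nkx2-5, the 10 largest rises and the 10 largest falls, the 3 members of each list with the smallest p, and 5 sex-linked genes. The largest changes were taken among genes with an adjusted p under 0.05, a mean of at least 1 CPM and both mutant libraries beyond both control libraries, leaving out gene models and pseudogene symbols. Adarb2 was not analysed here. Genes outside this rule that are named where a count of 5 or fewer needs them were chosen after their values were seen. Some genes that these rules name are not reported here.

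The alternatives were other scalings, filters, pseudocounts, thresholds and tests, each library left out in turn, and sex-chromosome genes left out. Count tests (edgeR 4.0.16, DESeq2 1.42.0, limma-voom) ran on the recovered reads. The edgeR quasi-likelihood test called 4641 genes with the authors' effective library sizes, and 4731 with TMM scaling, the edgeR filter and a robust fit. These 2 tests, TMM scaling, removal of the trend with transcript length and the restriction to protein-coding genes were chosen after seeing the data. The tests were tried on counts simulated for 14869 genes with 200 of them changed. Limma-trend called 83% of the 2-fold and 99% of the 4-fold changes, and 7 of the unchanged genes. With no change simulated it called 0 genes, and camera called 0 lists. The simulated genes varied independently, with the same dispersion in both groups. In the data the estimated correlation reached 0.932 in oxidative phosphorylation, and the mutants differed more than the controls. The simulation thus does not show how often camera calls a list falsely in these data.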

Results

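Poly(A) RNA of whole hearts was sequenced from 4 mouse embryos at E18.5, 2 controls without Nkx2.5-Cre (embryos 47 and 50) and 2 with it (embryos 51 and 54), all homozygous for floxed Adar1. The comparison asks how heart gene expression differs between floxed Adar1 embryos with and without Nkx2.5-Cre. Only the mutants carried the Cre allele, so its own effects and those of targeting Adar1 cannot be told apart. Between 7457103 and 8998872 reads per library fell on the listed genes, and 1 read was worth between 0.109 and 0.138 CPM. Correlation of log2(CPM + 1) across genes was 0.989 between the controls, 0.976 between the mutants and between 0.871 and 0.912 across the groups. The first principal component held 86.9% of the variance and placed the controls at -53.7 and -51.6 and the mutants at 63.2 and 42.1. Mutant 51 thus lay farther from the controls than mutant 54. Mitochondrial transcripts made up 6.14% and 6.93% of the reads in the controls, 2.08% in mutant 51 and 4.31% in mutant 54. Hemoglobin made up 0.536% and 1.24% in the controls, 0.0704% in mutant 51 and 0.497% in mutant 54. Ddx3y, a Y-linked gene, lay between 88.7 and 136 CPM in all 4 libraries, and Xist, transcribed from the inactive X chromosome, averaged 1.42 ± 1.52 CPM in the controls and 1.55 ± 1.35 CPM in the mutants (SD, n = 2 each). Eif2s3y and Kdm5d, also Y-linked, lay between 33.2 and 102 CPM. Uty rose by 0.82 (SE 0.22, adjusted p = 0.0279), and it was the only 1 of 5 members of the sex list past the threshold, over all genes and adjusted over the list alone. It was at 0.51 without control replicate 47, and not past the threshold without either control or without mutant replicate 54, and 2 members of the list rose without mutant replicate 51.

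Adar, the targeted gene (ENSMUSG00000027951, chromosome 3, 89715022 to 89753446), was higher in the libraries labelled mutant. It stood at 33.0 ± 3.85 CPM in the controls and 204 ± 13.03 CPM in the mutants (SD, n = 2 each). The log2 fold change was 2.60 (SE 0.13, limma adjusted p = 2.41e-05). The labels do not say which exons are floxed, and gene-level reads include exons left in place, so this value does not check the deletion. It goes against a loss of the gene's reads. The labels' genotype entry for both Cre-positive embryos reads wildtype and KO at once, so the groups rest on the sample titles, which the deposited column headers match, and every direction given here is that of the libraries labelled mutant against those labelled control. Nkx2-5, the gene whose name the Cre allele carries (chromosome 17, 26838664 to 26845009), fell from 147 ± 5.39 to 81.0 ± 16.7 CPM, a log2 fold change of -0.86 (SE 0.16, adjusted p = 0.0080). The Nkx2-5 call was lost without control replicate 47 (adjusted p = 0.121) and without control replicate 50 (adjusted p = 0.0986), with a range over the alternatives from 6.36e-05 to 0.121. Adarb1, which encodes another RNA-editing deaminase, had a log2 fold change of -0.21 (SE 0.16, adjusted p = 0.349). Its values overlapped between the groups, at 29.8 and 35.3 CPM in mutants 51 and 54 against 33.8 and 41.8 CPM in controls 47 and 50.

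In the libraries labelled mutant, 40 of 40 interferon-stimulated genes, 17 of 17 genes of MHC class I antigen presentation and 26 of 28 genes of the integrated stress response rose. Of the genes tested, 25 of 28 of nuclear-encoded oxidative phosphorylation, 20 of 30 of fatty acid oxidation and 23 of 40 of the cell cycle fell, while 2 of fatty acid oxidation and 1 of the cell cycle rose. The adjusted p of these 6 lists, past the threshold with camera's preset correlation, lay between 0.373 and 0.551 with an estimated correlation. The estimated form keeps few residual degrees of freedom with 4 libraries, so a high adjusted p from it neither supports a list nor argues against it. Double-stranded RNA sensing had an estimated correlation of 0.00298, below the preset 0.01. Even so, its unadjusted camera p was 0.0342 with that estimate, against 5.13e-07 with the preset. Of 14869 genes tested, 4750 changed, 2643 up and 2107 down, and 1146 of the rises and 604 of the falls were 2-fold or more. The 2 groups did not overlap for 72.2% of genes, against 33.3% by chance. Among protein-coding genes 2360 rose and 1945 fell. The genes that rose numbered 2251 with upper-quartile scaling and 2188 with quantile normalization, and the genes that fell 2937 and 2738, so the balance of rises against falls depends on the scaling. Without control replicate 47 the count was 571 (534 up, 37 down) and without control replicate 50 it was 669 (593 up, 76 down), with the spread then taken from the mutants and the lone control assumed to vary like them. The naming rule required both mutants beyond both controls for the largest changes and took most other genes by smallest p. Largely through that selection, all 116 named genes past the threshold had both mutants beyond both controls. Of these, 36 of 57 that rose and 7 of 59 that fell stayed past it with each library left out in turn. The authors' deposited table has 4615 genes at an FDR under 0.05, and 4549 of these were also called here. Of 34 gene lists tested with camera 27 passed, 11 up and 16 down. With an estimated correlation 0 passed, and 3 had an unadjusted p under 0.05, while fry passed 8. Up, these were interferon-stimulated genes, double-stranded RNA sensing, MHC class I antigen presentation, the integrated stress response and immediate early genes. Down, they were neutrophil and mast cell, Schwann cell and neuronal, and lung and airway markers. Fry did not pass oxidative phosphorylation (fry adjusted p = 0.131), fatty acid oxidation (0.121) or the cell cycle (0.168). Ranges of a list's adjusted p given here are over the alternatives that keep camera's preset correlation.

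**Figure D1:**
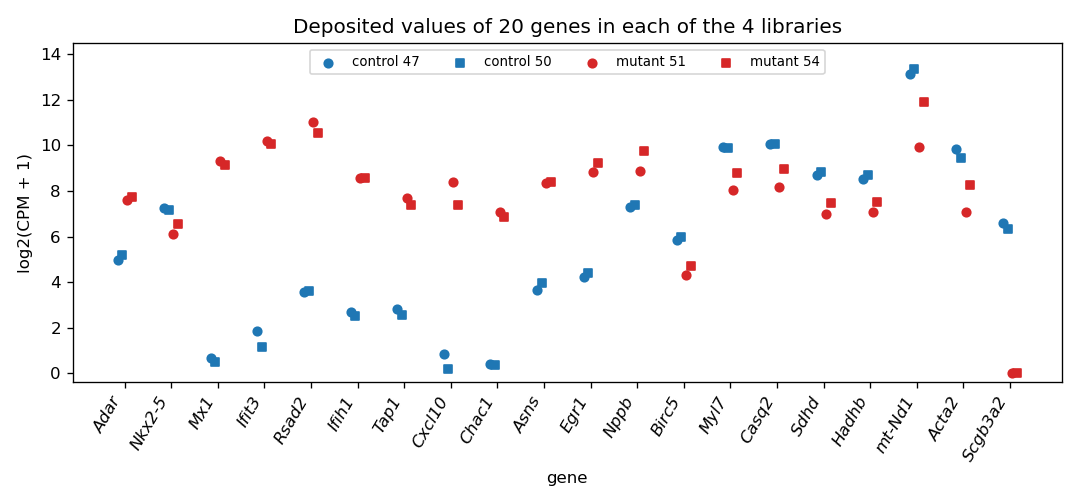
Log2(CPM + 1) of 20 genes (y axis) in each library, with control libraries in blue and mutant libraries in red, and 1 point per library with no averaging. Adar stands higher in both mutant libraries (194.9 and 213 CPM) than in both controls (30.2 and 35.7 CPM), and Scgb3a2 is at 0 in both mutant libraries.

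All 40 interferon-stimulated genes rose, with a median log2 fold change of 5.46, and 40 did so adjusted over the list alone. Mx1, which encodes an antiviral GTPase (chromosome 16, 97447035 to 97462907), went from 0.495 ± 0.113 to 596 ± 46.2 CPM, a log2 fold change of 8.64 (SE 0.14, adjusted p = 8.48e-07). The other largest rises were those of Ifit3, Ifit1, Mx2, Ifit3b, Usp18, Cxcl10, Isg15, Ifi44 and Rsad2, with log2 fold changes from 8.62 down to 7.19. Ifit3 and Ifit3b are close paralogs and their reads may be split uncertainly. Ifit2 rose by 5.64 (SE 0.11). Reads of the list made up 0.0418% and 0.0485% of the controls, 2.05% of mutant 51 and 1.75% of mutant 54. Camera gave an adjusted p of 2.82e-41 with the preset correlation, and adjusted p = 0.373 with an estimated correlation.

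Of 16 genes of double-stranded RNA sensing, 10 rose and none fell, and 11 rose adjusted over the list alone. Ifih1, which encodes the sensor MDA5, rose by 5.99 (SE 0.13), Ddx58, which encodes RIG-I, by 4.44 (SE 0.13) and Tlr3, an endosomal RNA receptor, by 3.54 (SE 0.17). The median was 2.01 (camera adjusted p = 2.18e-06, and adjusted p = 0.373 with an estimated correlation). All 17 genes of MHC class I antigen presentation rose, over all genes and adjusted over the list alone, with a median of 4.03. Tap1, a peptide transporter, rose by 4.87 (SE 0.16), Nlrc5, a regulator of the pathway, by 6.14 (SE 0.22) and Psmb8, an immunoproteasome subunit, by 5.08 (SE 0.22). The camera adjusted p was 1.55e-15, and adjusted p = 0.373 with an estimated correlation. H2 genes are near-identical copies and single members are uncertain. Of 16 tested cytokine and chemokine genes 11 rose, and 14 adjusted over the list alone, with a median of 1.51, and the same median with the 1 gene at 0 in the controls at its bound. Cxcl10, a chemokine for T cells, rose by 7.39 (SE 0.35), Socs1, an inhibitor of cytokine signalling, by 2.83 (SE 0.21) and Relb, an NF-kappaB subunit, by 2.71 (SE 0.24). Its adjusted p was 2.18e-06, and adjusted p = 0.528 with an estimated correlation. Without either control, 4 of the cytokine genes were past the threshold, and without mutant replicate 51 the list's median was 1.01.

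Of 28 genes of the integrated stress response 26 rose, and 27 adjusted over the list alone, with a median of 2.93. Chac1, which encodes a glutathione-degrading enzyme, went from 0.311 ± 0.0483 to 125 ± 15.4 CPM, a log2 fold change of 6.58 (SE 0.19). Asns, asparagine synthetase, rose by 4.57 (SE 0.14) and Mthfd2, a mitochondrial folate enzyme, by 3.62 (SE 0.12). Camera's adjusted p was 9.96e-22, and adjusted p = 0.377 with an estimated correlation. Of 18 endoplasmic reticulum chaperone and unfolded protein response genes, Herpud1 rose by 1.33 (SE 0.11) and Pdia6 fell by 0.45 (SE 0.13), and 1 rose and 0 fell adjusted over the list alone. Without mutant replicate 51 there were 4 falls in this list, and without mutant replicate 54 there were 3 rises. Xbp1 had a log2 fold change of 0.51 (SE 0.17, adjusted p = 0.0580), and the list was not past the threshold (adjusted p = 0.597). Xbp1 stood at 141 CPM in mutant 51 and 99.8 CPM in mutant 54, against 84.4 and 81.7 CPM in the controls.

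Of 22 immediate early genes 16 rose, over all genes and adjusted over the list alone, with a median of 1.40. Atf3 rose by 4.78 (SE 0.16), Egr1 by 4.73 (SE 0.16) and Ier2 by 1.82 (SE 0.12). Camera gave an adjusted p of 4.26e-07, and adjusted p = 0.373 with an estimated correlation. Without either control, 7 of these genes were past the threshold. Of 22 p53 targets 10 rose and 2 fell, against 12 and 2 adjusted over the list alone, with a median of 0.84. Plk2 rose by 1.81 (SE 0.11) and Btg2 by 2.09 (SE 0.18), while Perp fell by 1.31 (SE 0.14) and Sesn1 also fell. The list passed at an adjusted p of 0.00382, with adjusted p = 0.654 with an estimated correlation. It had 3 rises without control replicate 47, 2 without control replicate 50 and 15 without mutant replicate 54. Its median was 0.40 without mutant replicate 51 and 1.37 without mutant replicate 54. Of 24 cell death genes 8 rose and 3 fell, Casp6 and Diablo among them, against 11 and 4 adjusted over the list alone. Tnfsf10, a death receptor ligand, rose by 4.28 (SE 0.23), Mlkl, the executor of necroptosis, by 3.46 (SE 0.30) and Casp4, an inflammatory caspase, by 2.38 (SE 0.28). The median was 0.41 (adjusted p = 0.0392, and adjusted p = 0.506 with an estimated correlation). This adjusted p ranged over the alternatives from 0.0193 to 0.122, and the call ended without mutant replicate 51, with a filter at 5 CPM and with the length trend removed. Without either control 3 of the list rose and 0 fell, and without mutant replicate 51 the median was 0.18.

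Of 16 heat shock genes 4 rose, over all genes and adjusted over the list alone, namely Hspa1a, Hspb8 by 1.21 (SE 0.27), Hsp90aa1 by 0.83 (SE 0.19) and Bag3 by 0.48 (SE 0.12). The median was 0.25 (adjusted p = 0.0474, and adjusted p = 0.699 with an estimated correlation). Over the alternatives its adjusted p ranged from 0.000254 to 0.302, and the call ended without either control, without mutant replicate 51, and with upper-quartile scaling, a filter at 5 CPM and both edgeR quasi-likelihood tests. Without either control 0 members were past the threshold, and without mutant replicate 54 there were 8. The median was 0.11 without mutant replicate 51, when Hspb8 stood at 0.76, and 0.40 without mutant replicate 54. Of 8 tested replication-dependent histone genes 7 rose, over all genes and adjusted over the list alone, with a median of 1.64. Hist1h1c rose by 2.36 (SE 0.27), Hist1h1d by 3.08 (SE 0.36) and Hist1h3c by 1.71 (SE 0.33). Histone genes are near-identical copies, and poly(A) selection leaves out most of their transcripts. Camera's adjusted p was 0.00310, and adjusted p = 0.506 with an estimated correlation. Without control replicates 47 and 50, 1 and 2 members rose. Of 40 cell cycle genes 23 fell and 1 rose (Ccnd2, a G1 cyclin), against 26 and 2 adjusted over the list alone, with a median of -0.67. Birc5, which encodes survivin, fell by 1.41 (SE 0.17), Ccnb2, a mitotic cyclin, by 1.28 (SE 0.19) and Rrm1, a ribonucleotide reductase subunit, by 0.99 (SE 0.15). The list passed at an adjusted p of 1.25e-06, with adjusted p = 0.551 with an estimated correlation. Without either control 0 members were past the threshold. Without mutant replicate 51 the median was -0.40 and 18 members fell, and without mutant replicate 54 it was -0.81 and 30 fell.

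Of 28 nuclear-encoded oxidative phosphorylation genes 25 fell and none rose, and 26 fell adjusted over the list alone, with a median of -0.97. That median was -0.71 without mutant replicate 51 and -1.24 without mutant replicate 54. Sdhd and Sdhc, subunits of complex II, fell by 1.53 (SE 0.18) and by 1.47 (SE 0.19), and Ndufb8, of complex I, fell by 1.11 (SE 0.15). Camera gave an adjusted p of 3.91e-10, and adjusted p = 0.551 with an estimated correlation. Of 30 tested fatty acid oxidation genes 20 fell and 2 rose (Acot2 and Ppargc1a), against 22 and 3 adjusted over the list alone, with a median of -0.75. That median was -0.61 without mutant replicate 51 and -0.95 without mutant replicate 54. Etfdh fell by 1.17 (SE 0.13), Acads by 1.41 (SE 0.16) and Hadhb by 1.32 (SE 0.17). The list passed at an adjusted p of 8.41e-06, with adjusted p = 0.528 with an estimated correlation. Of 10 tested mitochondrial genome transcripts 5 fell, and 6 adjusted over the list alone, with a median of -1.56. Mt-Nd1 fell by 2.31 (SE 0.64), mt-Nd2 by 1.99 (SE 0.54) and mt-Nd6 by 1.60 (SE 0.42), and mt-Cytb and mt-Nd4 fell too. Without mutant replicate 51 the log2 fold changes of the first 3 were -1.30, -1.09 and -0.94. The list's adjusted p of 0.00586 became adjusted p = 0.551 with an estimated correlation. This adjusted p ranged over the alternatives from 8.74e-05 to 0.0574, and quantile normalization ended this call. The median was -0.81 without mutant replicate 51 and -2.26 without mutant replicate 54. Mitochondrial reads made up 2.08% of mutant 51 and 4.31% of mutant 54, against 6.14% and 6.93% of the controls. The mitochondrial tRNA gene mt-Te, among the largest falls, stood at 1.52 CPM in mutant 51 and 24.0 CPM in mutant 54, against 81.7 and 73.2 CPM in the controls. Its log2 fold change was -3.30 (SE 0.89), -1.65 without mutant replicate 51 and -4.96 without mutant replicate 54. Without either control, 1 fatty acid oxidation gene and 0 genes of the other lists of respiration were past the threshold.

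Of 31 glycolysis and hypoxia genes 11 fell and 3 rose (Hk2, Car12 and Vegfa), against 13 and 3 adjusted over the list alone. Pdk1, which inhibits pyruvate dehydrogenase, fell by 1.23 (SE 0.14) and Egln1, an oxygen-sensing hydroxylase, by 0.83 (SE 0.12), while Hk2, a hexokinase, rose by 1.27 (SE 0.17). The median was -0.51 (adjusted p = 0.00772, and adjusted p = 0.551 with an estimated correlation). Over the alternatives its adjusted p ranged from 0.000101 to 0.113, and the call ended without mutant replicate 54 and with quantile normalization. Without control replicates 47 and 50, 0 and 1 members rose and 1 fell in each case, and without mutant replicate 54 there were 6 rises and the median was -0.33. Of 32 ribosomal protein genes 4 fell, over all genes and adjusted over the list alone, with a median of -0.21. Rpl11 fell by 0.64 (SE 0.13), Rps4x by 0.83 (SE 0.18) and Rps15 by 0.54 (SE 0.13), and Rpl10 fell too. The list's adjusted p of 0.00370 became adjusted p = 0.671 with an estimated correlation. This adjusted p ranged over the alternatives from 2.78e-05 to 0.144, and the call ended without control replicate 50 and with quantile normalization and the length trend removed. Without either control 0 members were past the threshold, and without mutant replicate 54 there were 8. The median was -0.32 without mutant replicate 51 and -0.12 without mutant replicate 54.

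Of 28 sarcomere genes 7 fell and 3 rose, over all genes and adjusted over the list alone, with a median of -0.50. Myl7, the atrial myosin light chain, fell by 1.51 (SE 0.25), while Lmod2, a leiomodin of the thin filament, rose by 1.60 (SE 0.20), Myoz2 by 0.72 (SE 0.12) and Myom2 too. The list's adjusted p of 0.0474 became adjusted p = 0.716 with an estimated correlation. Over the alternatives its adjusted p ranged from 0.000781 to 0.980, and the call ended without control replicate 47, without mutant replicate 51, with upper-quartile scaling, quantile normalization and a filter at 5 CPM, and among protein-coding genes only. Without mutant replicates 51 and 54, 3 and 15 sarcomere genes fell. The list's median was -0.26 without control replicate 47, -0.30 without mutant replicate 51 and -0.73 without mutant replicate 54. Of 25 tested calcium handling and ion channel genes 9 fell, against 10 down and 1 up adjusted over the list alone. Casq2, a calcium buffer of the sarcoplasmic reticulum, fell from 1079 ± 0.214 to 397 ± 153 CPM, and the potassium channel genes Kcnd2 and Kcnj2 fell by 1.78 (SE 0.28) and by 0.65 (SE 0.12). The median was -0.48 (adjusted p = 0.00382, and adjusted p = 0.699 with an estimated correlation). This adjusted p ranged over the alternatives from 2.21e-08 to 0.0966, and the call ended without mutant replicate 51. Without mutant replicate 54, 18 of these genes fell, and without mutant replicate 51 there were 3 rises. The medians without these libraries were -0.84 and -0.13. Kcnip2, a channel subunit, Mb, which encodes myoglobin, and Dhrs7c were among the largest falls, at -3.04 (SE 0.71), -3.09 (SE 0.65) and -2.86 (SE 0.66), and at -1.73, -1.88 and -1.64 without mutant replicate 51.

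Of 29 tested cardiac transcription factor genes 7 rose and 5 fell, over all genes and adjusted over the list alone. Gata4 rose by 0.95 (SE 0.14), and Hopx fell by 1.29 (SE 0.25), and Nkx2-5, Hey2 and Smyd1 were also among the falls. The list was not past the threshold (adjusted p = 0.665). Of 19 tested heart muscle stress markers 7 rose, over all genes and adjusted over the list alone, with a median of 0.20. That median was 0.12 without mutant replicate 51 and 0.51 without mutant replicate 54. Nppb, a natriuretic peptide gene, rose by 1.99 (SE 0.26), Xirp2 by 2.18 (SE 0.15) and Rcan1, a calcineurin regulator, by 1.84 (SE 0.13). The list's adjusted p of 0.0392 became adjusted p = 0.551 with an estimated correlation. Over the alternatives its adjusted p ranged from 0.00609 to 0.151, and the call ended without control replicate 50, without mutant replicate 51 and with a filter at 5 CPM. Without either control, 2 of the stress markers and 0 genes of the other 3 heart muscle lists were past the threshold.

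**Figure D2:**
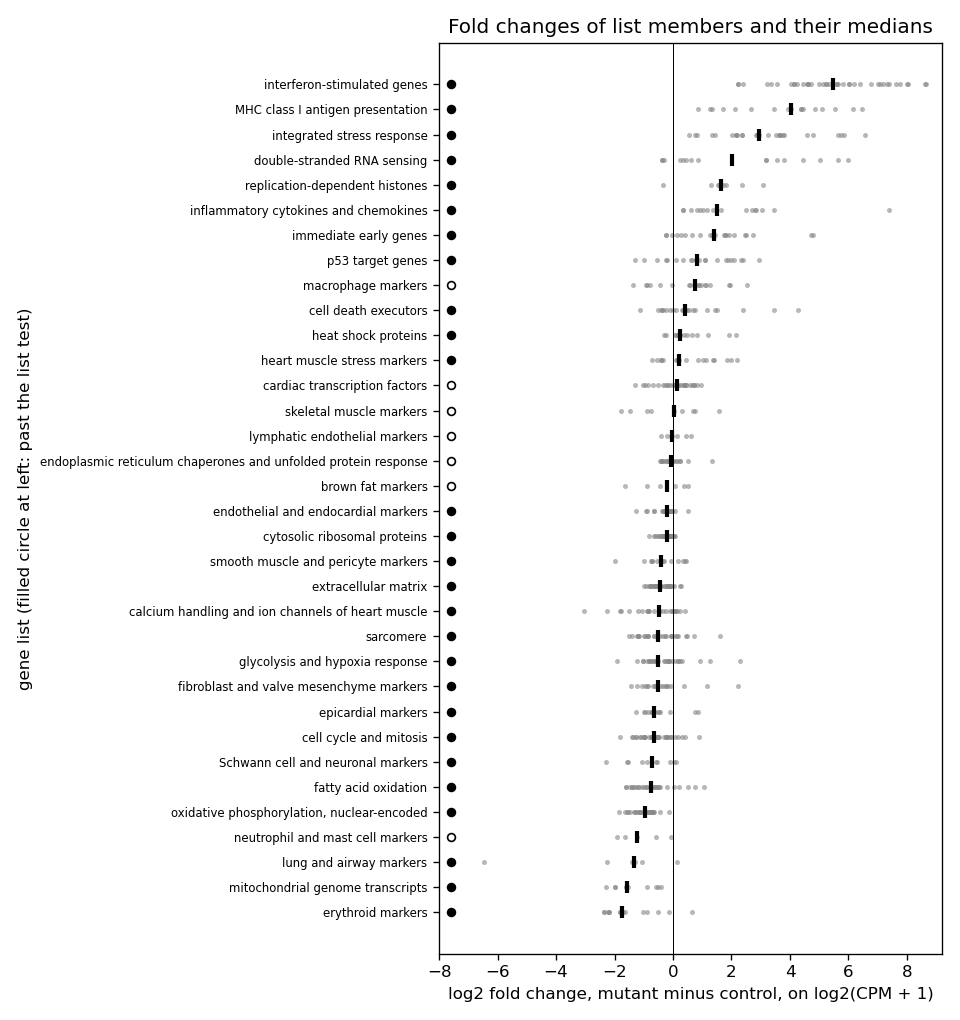
Log2 fold changes, mutant minus control on log2(CPM + 1) (x axis), of the tested members of 34 gene lists (y axis), with 1 grey point per gene, a black bar at each median and a filled circle where the list passed camera's test. Interferon-stimulated genes have the highest median, 5.46, and erythroid markers stand at -1.75, or -0.75 without mutant replicate 51.

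Of 32 extracellular matrix genes 12 fell, and 14 adjusted over the list alone. Lum fell by 0.81 (SE 0.14), Lox by 0.91 (SE 0.16) and Mmp2 by 0.59 (SE 0.12). The median was -0.44 (adjusted p = 0.000193, and adjusted p = 0.373 with an estimated correlation). Of 18 fibroblast and valve markers 8 fell and 2 rose, over all genes and adjusted over the list alone. Ddr2, a collagen receptor, rose by 2.22 (SE 0.21) and Scx by 1.16 (SE 0.20), while Gsn fell by 1.23 (SE 0.25). This list had a median of -0.52 (adjusted p = 0.0279, and adjusted p = 0.528 with an estimated correlation). Its adjusted p ranged from 0.0180 to 0.0985 over the alternatives, and the call ended without mutant replicate 51, when 2 markers fell, and with quantile normalization and both edgeR quasi-likelihood tests. Of 15 epicardial markers 7 fell, and 9 adjusted over the list alone, among them Upk3b by 0.95 (SE 0.18), Aldh1a2 by 0.71 (SE 0.15) and Muc16 by 1.26 (SE 0.26). Camera's adjusted p was 0.00363, and adjusted p = 0.551 with an estimated correlation, and without mutant replicate 54 there were 2 rises.

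Of 24 endothelial markers 4 fell and 1 rose (Nfatc1), against 1 and 0 adjusted over the list alone. Fabp4 fell by 0.88 (SE 0.15), Aplnr by 1.28 (SE 0.35) and Sox18 by 0.65 (SE 0.18), and Sox17 fell too. The median was -0.19 (adjusted p = 0.0180, and adjusted p = 0.656 with an estimated correlation). This adjusted p ranged over the alternatives from 0.000437 to 0.275, and the call ended without control replicate 50, without mutant replicate 51, when 2 markers fell, and with both edgeR quasi-likelihood tests. The median was -0.12 without control replicate 50, and Aplnr stood at -0.68 without mutant replicate 51. Of 15 smooth muscle and pericyte markers 5 fell, against 8 down and 1 up adjusted over the list alone. Acta2 fell by 1.98 (SE 0.36), Smtn by 0.72 (SE 0.15) and Myh11 from 28.7 ± 6.14 to 13.8 ± 2.29 CPM, and Mylk and Rgs5 fell too. Its median was -0.42 (adjusted p = 0.0392, and adjusted p = 0.513 with an estimated correlation). This adjusted p ranged from 0.0206 to 0.0578, and the call ended without control replicate 50 and with quantile normalization and both edgeR quasi-likelihood tests. Without mutant replicate 51 3 of these markers fell, and without mutant replicate 54 8 fell and 3 rose. Without either control, at most 1 member of each list of matrix, fibroblast, epicardial, endothelial and smooth muscle genes was past the threshold.

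Of 10 tested Schwann cell and neuronal markers 5 fell, over all genes and adjusted over the list alone, with a median of -0.73. Stmn2 fell by 2.31 (SE 0.45), Prph by 1.54 (SE 0.34) and Gap43 by 0.88 (SE 0.20), and Dbh and Ngfr fell too. The list's adjusted p of 0.0168 became adjusted p = 0.487 with an estimated correlation. Over the alternatives its adjusted p ranged from 0.00932 to 0.113, and a filter at 5 CPM ended the call. Of 14 tested erythroid markers 3 fell and 1 rose, over all genes and adjusted over the list alone, with a median of -1.75. Tfrc, the transferrin receptor gene, fell by 1.80 (SE 0.13), and Bpgm by 1.82 (SE 0.50), and Hba-x fell too. Camera gave an adjusted p of 0.00370, and adjusted p = 0.633 with an estimated correlation. Hemoglobin reads made up 0.0704% of mutant 51 and 0.497% of mutant 54, against 0.536% and 1.24% of the controls, and without mutant replicate 54 11 erythroid markers fell and 0 rose. Without mutant replicate 51 the erythroid median was -0.75 and Bpgm stood at -0.98. Of 19 tested macrophage markers 9 rose and 3 fell (F13a1, Mrc1 and Pf4), against 10 and 3 adjusted over the list alone. Fcgr1, an immunoglobulin receptor gene, rose by 2.55 (SE 0.36), Ptprc by 1.92 (SE 0.34) and C1qc by 0.87 (SE 0.16). The list was not past the threshold (adjusted p = 0.0792), with a range over the alternatives from 0.00960 to 0.296, and it passed without mutant replicate 54. Without mutant replicate 51 4 of the macrophage markers rose. Without either control, 0 macrophage and Schwann cell markers and 1 erythroid marker were past the threshold.

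Lung and airway markers fell in 5 of 6 tested cases, over all genes and adjusted over the list alone, with a median of -1.35 and the same median with Scgb3a2 at its bound. Scgb3a2, an airway secretory protein gene (chromosome 18, 43764289 to 43767399), stood at 95.3 and 79.9 CPM in the controls and 0 in both mutants, at least 246-fold lower against a floor of 3 reads per library. Foxj1, a regulator of motile cilia, fell by 2.24 (SE 0.34), as did Hopx, which the cardiac list also holds, Cdh1 and Sftpb. Camera's adjusted p was 0.00370, and adjusted p = 0.403 with an estimated correlation. Of the other largest falls, Reg3g was at least 37.8-fold lower and Cyp2f2 at least 30.7-fold lower. Muc5b, a mucin gene, had 3 reads over both mutant libraries and a ratio of control to mutant of 137 (95% counting interval 46.4 to 666). Scgb3a1 had 2, with a ratio of 99.5 (27.1 to 828). Cbr2 fell from 25.1 ± 6.68 to 1.25 ± 0.0839 CPM. Without either control, 1 member of the list was past the threshold, and 6 of the 10 largest falls were.

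The remaining lists were not past the threshold. Of 5 tested neutrophil and mast cell markers, the mast cell protease genes Tpsb2 and Cma1 fell by 1.92 (SE 0.48) and by 1.63 (SE 0.49), and 3 fell adjusted over the list alone. Cpa3 had a log2 fold change of -1.23 (SE 0.39, adjusted p = 0.0511). It stood at 15.1 CPM in control 47 and 5.81 CPM in control 50, against 3.59 and 3.32 CPM in the mutants. The list's adjusted p was 0.0581, with a range over the alternatives from 0.0274 to 0.128, and it passed without either control, with library sizes alone and with fry (adjusted p = 0.0461). Without control replicate 47 and without mutant replicate 51, 0 of these markers were past the threshold, and without the former Tpsb2 and Cma1 stood at -1.18 and -0.90. Of 7 tested lymphatic markers, Flt4 rose by 0.61 (SE 0.17) and Prox1 by 0.44 (SE 0.13), both over all genes and adjusted over the list alone, and Pdpn had a log2 fold change of -0.40 (SE 0.25). Pdpn stood at 19.7 CPM in mutant 51 and 12.2 CPM in mutant 54, against 23.4 and 18.4 CPM in the controls. The lymphatic list's median was -0.02 and its mean 0.07, and camera's direction was up (adjusted p = 0.771). Without either control or mutant replicate 54, 0 lymphatic markers were past the threshold, and without mutant replicate 51 there was 1. Their median ranged from -0.37 without control replicate 50 to 0.33 without control replicate 47, when Flt4 stood at 0.38. Of 9 tested skeletal muscle markers 1 rose and 2 fell, over all genes and adjusted over the list alone. Tnnt3 rose by 1.57 (SE 0.28), while Ckm fell by 1.80 (SE 0.45) and Myl1 by 0.89 (SE 0.27). The median was 0.02, while the mean was -0.17 and camera's direction was down (adjusted p = 0.727). Without either control 0 of these muscle markers fell, and without mutant replicate 54 there were 4 falls. The median ranged from -1.002 without mutant replicate 54 to 0.37 without mutant replicate 51. Ckm stood at -1.05 and Myl1 at -0.45 without mutant replicate 51, and Myl1 at -1.34 without mutant replicate 54. Of 6 tested brown fat markers Prdm16 rose by 0.50 (SE 0.14), and Fabp4 and Cox7a1 fell, over all genes and adjusted over the list alone, and 0 were past the threshold without either control (list adjusted p = 0.597). Lymphocyte, platelet and liver lists had 2 tested members each and were not tested as lists. Lck rose by 2.51 (SE 0.30), and Gzma had a log2 fold change of 1.52 (SE 0.54, adjusted p = 0.0688), with both past the threshold adjusted over the list alone. Gzma stood at 6.42 CPM in mutant 51 and 1.31 CPM in mutant 54, against 0.345 and 0.553 CPM in the controls. Clec1b and Itga2b stood at -0.70 (SE 0.40) and -0.28 (SE 0.28), and Apoh and Ahsg at 0.66 (SE 0.30) and 0.26 (SE 0.34), with 0 past the threshold over all genes or adjusted over the list alone. Clec1b was at 1.95 CPM in control 47 and 4.98 CPM in control 50, against 2.07 and 1.19 CPM in mutants 51 and 54. Apoh was at 2.30 and 1.94 CPM in these controls and at 3.05 and 4.99 CPM in these mutants. Of 770 antisense genes 117 rose and 59 fell, but the strand setting of the counting is not given, so reads of an antisense gene and its partner cannot be separated.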

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

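Alternatives chosen after seeing the data were TMM scaling, the 2 edgeR quasi-likelihood tests, removal of the length trend and the restriction to coding genes. The deposited scaling equals RLE, so the planned RLE alternative moved nothing. Counts of changed genes lay from 3674 (DESeq2) to 6476 (adjusted p under 0.1), apart from those given next. At an adjusted p under 0.01 there were 1863 (1292 up, 571 down), and with a fold change of at least 2 there were 1750 (1146 up, 604 down). With each library left out, changed genes, mutant against control, ranged from 571 to 5655, genes that rose from 534 to 2905 and genes that fell from 37 to 2750. The lowest values came from leaving out a control, when the spread comes from the mutant pair alone and the lone control is assumed to vary like it. No gene called in the main comparison was called in the other direction under any of these settings. The share of changed genes that rose was 55.6%, 43.4% with upper-quartile scaling, 44.4% with quantile normalization and 64.8% with library size only, and the median of all genes moved by less than 0.1 under each scaling.

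Of 34 lists 27 passed, between 20 and 28 under the other scalings, filters, tests of genes and left-out libraries. Fry, which tests each list without comparing it with other genes, passed 8, and an estimated inter-gene correlation passed 0, with 3 lists under an unadjusted p of 0.05. The estimated form has little power with 4 libraries, so its 0 decides nothing about a list. Adar kept its direction and call throughout, and Nkx2-5 ranged from -1.07 to -0.65 with a library left out. Directions turned only in lists and genes that were not past the threshold. With a library left out, the adjusted p ranged from 0.0965 to 0.634 for endoplasmic reticulum chaperones, from 0.180 to 0.808 for cardiac transcription factors, from 0.292 to 0.961 for lymphatic markers and from 0.113 to 0.961 for skeletal muscle markers. Direction turned without mutant replicate 54 (0.580 for both) in chaperones and cardiac factors, without control replicate 50 (0.641) and mutant replicate 51 in lymphatic markers, and without control replicate 47 (0.795) and mutant replicate 51 in skeletal muscle. It also turned with fry in chaperones and skeletal muscle (0.919 for both), with the edgeR quasi-likelihood tests in cardiac factors (0.966 and 0.979) and with the length trend removed in lymphatic markers (0.999). Log2 fold changes with a library left out ranged from -0.62 to 0.056 for Itga2b, from -0.17 to 0.70 for Ahsg, from -0.32 to 0.044 for Eif2s3y, from -0.30 to 0.013 for Kdm5d and from -0.56 to 0.81 for Xist, which was at -0.23 with quantile normalization and -0.11 with the length trend removed. The causes were not tested. Across list results, 507 were the same, 86 weaker and 5 stronger. Across named genes, 2304 were the same, 189 weaker and 20 stronger. Depth limits genes near 0.109 to 0.138 CPM, the worth of 1 read. No paired analysis was possible because the groups share no replicate numbers.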

Other observations

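The lists, genes and antisense pairs described first were chosen after seeing the data, and so were all tests of the 3 patterns described after them, except those on further airway and cartilage markers. Of 20 tested cytosolic aminoacyl-tRNA synthetase genes, which charge transfer RNAs, 17 rose and 1 fell, with a median log2 fold change of 1.74. Cars rose by 2.71 (SE 0.12) and Aars by 2.35 (SE 0.15), while Qars fell by 0.65 (SE 0.12). Of 17 mitochondrial synthetase genes 2 rose and 5 fell, with a median of -0.29. Camera, adjusted over the 6 added lists, gave 1.29e-10 for the cytosolic and 0.103 for the mitochondrial list, and adjusted p = 0.346 and 0.396 with an estimated correlation. The difference between the 2 lists was not tested. All 18 tested interferon-inducible GTPase genes rose, with a median of 4.90, or 5.05 with the 2 genes at 0 in the controls at their bound, among them Iigp1 at 6.44 (SE 0.14). Gbp3 is also in the interferon list, and Gbp and Tgtp genes are close paralogs. Tgtp2 and Gbp10 were at 0 in both controls, and were at least 178-fold and at least 36.3-fold higher against 3 reads per library. The adjusted p was 8.01e-20, and adjusted p = 0.0985 with an estimated correlation. Of 19 tested cholesterol synthesis genes 9 fell and 0 rose, with a median of -0.54, among them Idi1 by 1.18 (SE 0.22). The adjusted p was 0.00353, and adjusted p = 0.396 with an estimated correlation. Ifnb1, which encodes interferon beta, was at 0 in both controls and at 5.33 and 1.31 CPM in mutants 51 and 54 (adjusted p = 0.0262). It was singled out after its values were seen.

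Antisense genes with a coding partner on the other strand numbered 741. Their fold changes correlated with those of the partners at a Spearman's rho of 0.793 across genes, and the highest of 1000 shuffles gave 0.105. Of 113 such antisense genes that rose, 91 had a partner that rose, against 74 of the other 628. The strand setting of the counting is not given, so reads of both strands counted together stay open.

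Adar read higher in the libraries labelled mutant. A single wrong label is argued against, since 4 of 4 libraries correlated best with the other library of their own group. An exchange of the labels of both groups stays open, since the titles and the deposited column headers name the groups alike but the genotype entry of the Cre-positive embryos reads wildtype and KO at once, and the log2 fold change of Nkx2-5 was -0.86 but the labels do not say what the Cre allele does to that gene. Reads from exons left in place may rise with the interferon response, in which 37 of 40 interferon-stimulated genes rose more than Adar. Reads per exon were not analysed here, so the exchange and the exons left in place cannot be told apart.

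Nuclear-encoded oxidative phosphorylation genes fell by a median of 0.97. Fold changes rose with transcript length across 13001 coding genes (Spearman's rho 0.172, across genes, which are not independent replicates), from a median of -0.26 in the shortest decile to 0.17 in the longest. With that trend removed the list's median was -0.88 (95% bootstrap interval -1.09 to -0.72, genes taken as independent). The estimated correlation between these genes was 0.932, so the interval does not measure the spread between embryos. The median itself moved little when the trend was removed, which argues against the trend as the whole cause in these 4 libraries. Reads taken by induced genes would lower the other genes alike, but with library sizes alone, which do not centre the genes, the other 14841 had a median of 0.0829, or 0.0300 without mutant replicate 51. A lower share of heart muscle cells alone, with the other cell types unchanged, would raise the markers of those types. The 72 fibroblast, epicardial, endothelial and smooth muscle markers had a median of -0.37 (-0.57 to -0.24, genes taken as independent). It was -0.32 without mutant replicate 51 and -0.42 without mutant replicate 54. These values argue against that narrow case only. Cell types lowered together with heart muscle would escape this test. The pool also shares genes with heart lists, namely Des with the sarcomere list, Postn with the stress markers and Tbx18 with the cardiac transcription factors. A change brought by the genotype stays open and was not tested.

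Scgb3a2, Muc5b, Reg3g, Cyp2f2 and Scgb3a1 were at or near 0 in the libraries labelled mutant. Airway tissue left on the control hearts is a candidate source, but 13 further airway markers, of 40 listed, had a median log2 fold change of -0.63 (-0.90 to 0.02), between the bounds set for and against it, with 5 that fell and 1, Krt17, that rose. The bootstrap intervals here and for cartilage take genes as independent. Other airway genes fell, such as Wfdc2 by 2.64 (SE 0.26), but were picked after their values were seen and decide nothing. Cartilage that came with such tissue is argued against with all 4 libraries, since 7 markers had a median of 0.35 (-0.17 to 0.48), above the bound set before they were looked up, but this rests on mutant 51, without which the median was -0.27 and its interval, from -0.63, crossed that bound. Whether these genes differ through dissection or genotype cannot be told apart, since each group has 2 hearts and no label describes the dissection.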
